A study of Homo sapiens with 22 samples.

How the data were processed

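Expression was measured on Affymetrix arrays of 22283 probe sets in 22 samples of human PBMC, monocytes and cultured macrophages, 2 arrays in each of 11 groups. The deposited values are an intensity per probe set: per the labels the authors made them with MAS5, whose version is not given in the sources used here. The values were linear, and the 2%-trimmed mean of each array lay between 250.08 and 250.12, which is the authors' scaling. That scaling was kept, since the trimmed means differed by less than 1.2-fold. Array medians ran from 69.7 to 101. Scanner files and detection calls were not used here. For arrays, their number limits the precision.

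Probe sets were named with the platform's annotation table. Of them 19071 carried 1 gene symbol, 1043 several and 2169 none, and 68 were controls. Only probe sets with 1 symbol were used, and of several for a gene the one with the highest mean log2 value over all arrays, which gave 11939 genes. Gene identifiers were checked against a reference table for 19059 probe sets, and 0 symbols were updated. A gene was tested when its signal lay above the 40th percentile of the array in at least 2 arrays, which left 9638 genes. The annotation tables give no genome build used here, and positions are not reported.

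Values were analysed as log2(signal + 13.7), where 13.7 is the median over arrays of the 20th percentile of signal. limma 3.58.1 in R 4.3.3 was fitted to all 22 arrays with 1 mean per group and a variance prior with a trend (11 residual and 8.61 prior degrees of freedom). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested, from limma's 2-sided moderated test. All 11 groups share 1 estimate of the spread, because 2 arrays alone give too little. 16 contrasts were tested: 15 between pairs of groups and 1 difference of 2 effects, that of oxLDL after CXCL4 and after M-CSF. No covariate was used, since the labels give no batch. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

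27 gene lists were fixed before the data were examined, as were the contrasts, the tests, the rule for named genes and the other settings to be tried. They hold markers of monocytes, macrophage differentiation, dendritic cells, T cells, B cells, NK cells, platelets, erythroid cells and neutrophils, and MHC class II, chemokine receptors, scavenger receptors, LXR targets and cholesterol efflux, cholesterol synthesis and uptake, PPAR targets and lipid storage, oxidative stress response, metallothioneins, inflammatory cytokines and NF-kB targets, interferon-stimulated genes, matrix proteases and inhibitors, lysosome, coagulation, ER stress and amino acid response, heat shock, immediate early genes, hypoxia and glycolysis, and proliferation. Of 422 list genes, 57 were not analysed here. Lists with at least 5 measured members were tested with camera (preset correlation 0.01) against the other genes, 2-sided and adjusted over the lists of a contrast, and again with a correlation estimated for each list. fry was also run: it tests whether a list's genes move, on balance, one way, and compares the list with no other genes. Members called were also counted with p adjusted over the list alone. Some markers belong to more than 1 cell type, so a list does not measure a cell count.

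Named genes are, per contrast, the 6 called genes with the largest rise and the 6 with the largest fall for which both arrays of one group lay above both of the other, up to 4 called members of each list with the smallest adjusted p, up to 2 highest members of lists with fewer than 2 called (values only), and the ligands and receptors of the treatments, with the dendritic and MHC class II markers in the lipoprotein contrasts. For the difference of effects, where 4 groups enter, all called genes were eligible. The text names part of what the rule gives.

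The test was tried on simulated data with 200 of 9638 genes changed. For oxLDL against 8-day macrophages it called 16.4% of genes changed by 0.5 on the log2 scale, 55.2% by 1 and 92.4% by 2, with 6.84% of calls false. For the difference of effects it called 4.48%, 16.4% and 71.2%, with 4.69% false. Comparisons that share control arrays were set against 100 simulated pairs of unchanged groups with the same sharing, in which genes also vary independently. The other settings fixed beforehand were quantile normalization, scaling to a common median, no offset, an offset at the 40th percentile, no low filter, a filter at the 60th percentile, no trend in the prior, a fit on the compared arrays alone, the replicate number as a block, all 16606 probe sets tested one by one, a 2-fold minimum, and leaving out each array. 3 were added after seeing the data: a fit without the PBMC arrays, the mean T cell marker level of each array as a covariate, and, for the difference of effects, 6-day in place of 8-day M-CSF macrophages as the control of oxLDL.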

Results

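Gene expression was measured with 1 Affymetrix array per sample in human blood mononuclear cells and in cells cultured from them. The 22 arrays fell into 11 groups of 2. The first groups were peripheral blood mononuclear cells (PBMC), monocytes isolated from PBMC by negative selection, and monocytes cultured for 6 days with macrophage colony-stimulating factor (M-CSF, 100 nM), called 6-day macrophages. Such macrophages were given the chemokine CCL2 or CXCL1 (100 nM) for 5 hours or kept in M-CSF for 8 days. Others were given native low-density lipoprotein (LDL), minimally modified LDL (mmLDL) or oxidized LDL (oxLDL) at 100 µg/ml for 2 days. The last groups were monocytes cultured for 6 days with the platelet chemokine CXCL4 (100 nM) in place of M-CSF, without or with oxLDL (100 µg/ml) for 2 days. The cells came from mononuclear fractions pooled from 4 donors. The labels do not say whether the 2 arrays of a group came from separate cultures or pools, so the p-values may reflect technical spread only. Signals below are the mean ± SD over the 2 arrays of a group (n = 2), a difference is the log2 fold change with its SE, and p-values are from limma. For a gene list, the members that changed are counted over all genes tested and adjusted over the list alone, and the median is that of the log2 fold changes. camera's p-value is given for each list and, where camera called it, a p-value with an estimated correlation if that one misses 0.05. A signal under the 20th percentile of its array is not above background, and no pairwise log2 fold change is given where an array of either group lies there.

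The arrays of a group resembled each other closely, with Spearman correlations across genes of 0.953 to 0.985. PBMC arrays stood apart in RNA quality. Their ratio of 3' to 5' signal was 2.20 to 2.85 for actin and 2.05 to 2.69 for GAPDH, against 0.902 to 1.28 and 0.868 to 1.09 on the other 20 arrays. Cultured cells carried lymphocyte transcripts. The median T cell marker stood at 6.99% of its PBMC signal in monocytes, 72.8% in 6-day macrophages and 54.2% in 8-day macrophages. It stood between 18.5% (CXCL4 with oxLDL) and 43.0% (mmLDL) in the treated cultures. The 8-day arrays stood apart, the mean log2 level of T cell markers being 9.68 on array 2 and lower on array 1. B cell markers stood at 43.3% and 28.4% and NK cell markers at 79.2% and 110.5% in the 6-day and 8-day macrophages.

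**Figure D1:**
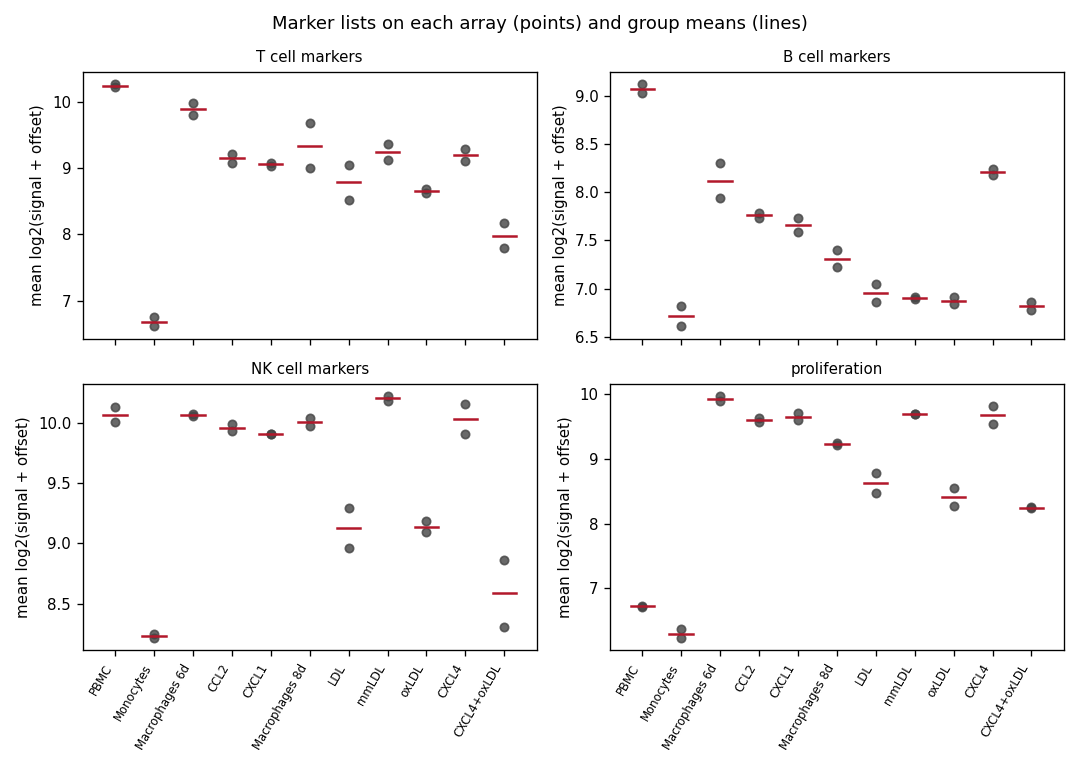
Mean log2(signal + offset) of T cell, B cell, NK cell and proliferation lists (y axis) on each array (points) of the 11 groups (x axis), with the group mean as a line. T cell marker means were 6.61 and 6.75 on the monocyte arrays and 9.80 and 9.99 on the arrays of 6-day macrophages.

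Isolated monocytes were set against PBMC. Inflammatory genes rose more than monocyte markers (median log2 4.36, 1.38), so more than selection differs. The interferon-induced chemokine CXCL10 went from 121 ± 34.1 to 15115 ± 722 (log2 fold change 6.84, SE 0.32, adjusted p = 1.17e-12), the monocyte chemoattractant CCL2 from 113 ± 44.2 to 9108 ± 35.6, and cyclooxygenase PTGS2 from 116 ± 16.9 to 6796 ± 406. Markers of the monocyte itself rose as well, with the lipopolysaccharide co-receptor CD14 going from 960.3 ± 145 to 9838 ± 1101 (log2 fold change 3.34, SE 0.29, adjusted p = 9.3e-09) and the M-CSF receptor CSF1R from 252 ± 76.0 to 1808 ± 110.3. Lymphocyte genes fell, such as the T cell receptor component CD3D (from 4332 ± 648 to 159 ± 22.1) and the cytokine IL32 (from 1345 ± 94.1 to 9.45 ± 0.354).

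17 of 19 inflammatory cytokine and NF-kB target genes rose and 1 fell (same adjusted over the list alone, median log2 4.36, camera adjusted p = 8.33e-15). 14 of 19 lysosome genes rose (same adjusted over the list alone, median log2 0.92, camera adjusted p = 1.55e-09). 11 of 20 interferon-stimulated genes rose and 3 fell (same adjusted over the list alone, median log2 0.51, camera adjusted p = 6.68e-05). 9 of 15 matrix protease and inhibitor genes rose (10 adjusted over the list alone, median log2 1.27, camera adjusted p = 1.72e-06). 9 of 14 monocyte markers rose and 1 fell (same adjusted over the list alone, median log2 1.38, camera adjusted p = 9.98e-05, adjusted p = 0.0556 with an estimated correlation). 6 of 12 MHC class II genes rose and 1 fell (same adjusted over the list alone, median log2 0.67, camera adjusted p = 0.00167, adjusted p = 0.0537 with an estimated correlation), with HLA-DRA (1.11) and HLA-DRB1 (1.22) as examples, and HLA-DOB, an antigen-loading gene of B cells, going from 268 ± 1.63 to 19.4 ± 11.4. 6 of 7 heat shock genes fell (same adjusted over the list alone, median log2 -1.31, camera adjusted p = 0.00954, adjusted p = 0.0591 with an estimated correlation), among them the chaperones HSPH1 (-3.07) and DNAJB1 (-2.38).

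16 of 16 T cell markers fell (same adjusted over the list alone, median log2 -3.56, camera adjusted p = 1.48e-10, adjusted p = 0.0591 with an estimated correlation). 9 of 10 B cell markers fell (same adjusted over the list alone, median log2 -2.38, camera adjusted p = 0.000484, adjusted p = 0.0537 with an estimated correlation). 10 of 11 NK cell markers fell (same adjusted over the list alone, median log2 -1.69, camera adjusted p = 6.68e-05, adjusted p = 0.121 with an estimated correlation). 11 of 12 platelet markers fell (12 adjusted over the list alone, median log2 -1.65, camera adjusted p = 0.00841, adjusted p = 0.0962 with an estimated correlation). 6 of 6 erythroid markers fell (same adjusted over the list alone, median log2 -2.24, camera adjusted p = 0.00434, adjusted p = 0.0853 with an estimated correlation). The median platelet marker remained at 31.3% of its PBMC signal. 7 of 12 neutrophil markers rose (8 adjusted over the list alone, median log2 1.34, camera adjusted p = 0.000643, adjusted p = 0.0538 with an estimated correlation), including the granule proteins lactoferrin (LTF, from 8.05 ± 3.46 to 659 ± 48.9) and cathelicidin (CAMP, from 25.2 ± 0.141 to 283 ± 33.6). 8 of 27 dendritic cell markers rose and 8 fell (same adjusted over the list alone, median log2 0.04 and mean -0.11, tested upward, camera adjusted p = 0.164). CD86, a costimulatory molecule, rose from 611 ± 62.9 to 4401 ± 201, and the endocytic receptor LY75 fell from 638 ± 60.4 to 46.4 ± 30.4. limma called 5170 of 9638 genes tested, 1533 higher and 3637 lower. Camera called 22 of 27 lists, 4 of them with an estimated correlation. The median log2 fold change of all genes was -0.40 under the deposited scaling, -0.11 after quantile normalization and 0.04 with a common median. Of the called genes, 29.7%, 43.8% and 57.4% were higher, in the same order. The PBMC arrays are also those with the high 3' to 5' ratios and CreX signals.

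6-day macrophages were compared with isolated monocytes. Monocyte markers fell: the lectin FCN1 went from 10089 ± 461 to 94.8 ± 4.24 (log2 fold change -6.54, SE 0.24, adjusted p = 2.74e-14), CD14 from 9838 ± 1101 to 19.8 ± 11.4 and the alarmin S100A9 from 8060.1 ± 1855 to 225 ± 16.5. Inflammatory genes fell too, IL1B from 16538 ± 1786 to 228 ± 4.81 and PTGS2 from 6796 ± 406 to 20.6 ± 3.39. Their list mean (log2 8.40 and 8.53) was back at the PBMC level (8.48 and 8.28). Rises included the lipoprotein component APOC1 (from 22.9 ± 4.81 to 1296 ± 80.4, log2 fold change 5.17, SE 0.15, adjusted p = 8.01e-15) and the mannose receptor MRC1 (from 51.7 ± 4.38 to 1714 ± 225). The oxLDL receptor OLR1 fell from 6194 ± 228 to 24.8 ± 0.354. The cholesterol exporter ABCA1 fell from 1850.1 ± 179 to 327 ± 56.9 and CSF1R from 1808 ± 110.3 to 314 ± 95.0.

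1 of 14 monocyte markers rose and 11 fell (same adjusted over the list alone, median log2 -4.03, camera adjusted p = 3.27e-08). 1 of 19 inflammatory cytokine and NF-kB target genes rose and 18 fell (same adjusted over the list alone, median log2 -2.78, camera adjusted p = 3.25e-13). 15 of 17 immediate early genes fell (16 adjusted over the list alone, median log2 -2.75, camera adjusted p = 3.25e-13). 16 of 18 cholesterol synthesis and uptake genes rose and 1 fell (same adjusted over the list alone, median log2 1.79, camera adjusted p = 4e-04), led by the methylsterol oxidase MSMO1 (from 21.1 ± 0.354 to 764 ± 48.2, log2 fold change 4.48, SE 0.19, adjusted p = 2.51e-13). 6 of 7 metallothioneins rose (same adjusted over the list alone, median log2 2.49, camera adjusted p = 4e-04, adjusted p = 0.0724 with an estimated correlation). 16 of 16 proliferation genes rose (same adjusted over the list alone, median log2 3.53, camera adjusted p = 1.5e-10), including the ribonucleotide reductase subunit RRM2 (from 76.3 ± 7.99 to 3826 ± 259.6) and the topoisomerase TOP2A (from 13.6 ± 3.68 to 895 ± 39.7). 1 of 9 coagulation genes rose and 6 fell (same adjusted over the list alone, median log2 -1.88, camera adjusted p = 0.000266), among them the clotting factor subunit F13A1 (from 2092 ± 46.6 to 20.9 ± 9.26). 3 of 11 scavenger receptors rose and 7 fell (same adjusted over the list alone, median log2 -1.06, camera adjusted p = 0.0168, adjusted p = 0.165 with an estimated correlation). 14 of 26 macrophage differentiation genes rose and 9 fell (same adjusted over the list alone, median log2 0.86, camera adjusted p = 0.459). 13 of 27 dendritic cell markers rose and 6 fell (14 and 6 adjusted over the list alone, median log2 0.77, camera adjusted p = 0.459), with the chemokine CCL22 rising from 213 ± 12.3 to 3015 ± 365 and CD83 falling from 6002 ± 853 to 1379.8 ± 124. 8 of 17 hypoxia and glycolysis genes rose and 7 fell (same adjusted over the list alone, median log2 0.14 and mean -0.26, tested downward, camera adjusted p = 0.379). 3 of 9 chemokine receptors rose and 4 fell (same adjusted over the list alone, median log2 -0.14 and mean 0.04, tested downward, camera adjusted p = 0.459).

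Lymphocyte markers rose alongside these groups. 16 of 16 T cell markers rose (same adjusted over the list alone, median log2 3.07, camera adjusted p = 5.46e-08, adjusted p = 0.139 with an estimated correlation). 10 of 11 NK cell markers rose and 1 fell (same adjusted over the list alone, median log2 2.19, camera adjusted p = 0.000773, adjusted p = 0.213 with an estimated correlation). 7 of 10 B cell markers rose (same adjusted over the list alone, median log2 1.43, camera adjusted p = 0.0391, adjusted p = 0.165 with an estimated correlation). Examples are CD3D (from 159 ± 22.1 to 3733 ± 123), the kinase LCK (from 54.8 ± 8.27 to 2447 ± 243), the B cell marker MS4A1 (from 70.7 ± 25.4 to 1204 ± 353) and granulysin (GNLY, from 490.0 ± 75.5 to 5590.1 ± 345). 11 of 12 platelet markers fell (12 adjusted over the list alone, median log2 -3.75, camera adjusted p = 4.44e-09), with platelet basic protein (PPBP) falling from 7395 ± 179 to 25.1 ± 3.11. limma called 5461 of 9638 genes tested, 3705 higher and 1756 lower. Camera called 16 of 27 lists, 8 of them with an estimated correlation. The median log2 fold change of all genes was 0.23 under the deposited scaling, 0.07 after quantile normalization and 0.06 with a common median. Of the called genes 67.8% were higher, and 57.8% after quantile normalization.

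Longer culture was read from 8-day against 6-day macrophages, both in M-CSF. The lipid-sensing macrophage receptor TREM2 rose from 35.8 ± 20.6 to 369 ± 28.9 (log2 fold change 3.02, SE 0.43, adjusted p = 0.000121), the sterol 27-hydroxylase CYP27A1 from 224 ± 53.9 to 1504 ± 179.9 and the monocyte marker CD14 from 19.8 ± 11.4 to 230.1 ± 76.8. LXR target and lipid storage genes rose, including the oxysterol receptor NR1H3 (from 418 ± 70.6 to 1884 ± 154, log2 fold change 2.15, SE 0.21, adjusted p = 3.75e-06), the cholesterol exporter ABCG1 (from 156 ± 2.26 to 509.6 ± 204), the desaturase SCD (from 863 ± 36.4 to 3256 ± 524) and the lipid droplet protein PLIN2 (from 1453 ± 105 to 2772 ± 403). Falls included the neutrophil chemokine CXCL8 (from 3479 ± 1222 to 1076 ± 141) and the mitotic regulator CDC20 (from 765 ± 16.4 to 330.0 ± 15.1).

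19 of 19 lysosome genes rose (same adjusted over the list alone, median log2 0.88, camera adjusted p = 4.89e-23), with the cholesterol transporter NPC1 going from 677 ± 120.2 to 2308 ± 252 and the hexosaminidase HEXA from 537 ± 103 to 1297 ± 102. 20 of 26 macrophage differentiation genes rose (22 adjusted over the list alone, median log2 1.11, camera adjusted p = 4.89e-23), among them APOC1 (1.70), GPNMB (1.83), CTSK (1.73) and C1QB (1.86). 5 of 14 monocyte markers rose and 1 fell (same adjusted over the list alone, median log2 0.29, camera adjusted p = 0.00742, adjusted p = 0.181 with an estimated correlation). 9 of 11 LXR target and cholesterol efflux genes rose (same adjusted over the list alone, median log2 1.09, camera adjusted p = 2.5e-12). 5 of 15 PPAR target and lipid storage genes rose (same adjusted over the list alone, median log2 0.59, camera adjusted p = 9.71e-05). 10 of 16 proliferation genes fell (13 adjusted over the list alone, median log2 -0.75, camera adjusted p = 8.83e-09). 4 of 10 B cell markers fell (6 adjusted over the list alone, median log2 -0.71, camera adjusted p = 9.71e-05). 3 of 16 T cell markers fell (6 adjusted over the list alone, median log2 -0.52, camera adjusted p = 0.000151, adjusted p = 0.301 with an estimated correlation), from 72.8% to 54.2% of the PBMC signal at the median. 2 of 27 dendritic cell markers rose and 3 fell (3 and 3 adjusted over the list alone, median log2 -0.26, camera adjusted p = 0.651), with the integrin ITGAX (CD11c) rising from 255 ± 54.7 to 824 ± 46.8, a call lost without Macrophages 6d 1 (1.44).

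limma called 984 of 9638 genes tested, 608 higher and 376 lower. Camera called 15 of 27 lists, 9 of them with an estimated correlation. The count was 405 without Macrophages 6d 1, 644 without Macrophages 6d 2 and 486 without Macrophages 8d 1, 542 from the 4 arrays alone and 368 with the T cell marker level as a covariate. The higher share was 61.8%, and 78.6% with a common median.

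CCL2, a chemokine tied to monocyte recruitment in atherosclerosis, was given for 5 hours and compared with untreated 6-day macrophages. APOC1 rose from 1296 ± 80.4 to 2777 ± 111 (log2 fold change 1.09, SE 0.15, adjusted p = 0.003), the scavenger receptor MSR1 from 160.4 ± 37.1 to 403 ± 63.4 and the glycoprotein GPNMB from 1693 ± 69.1 to 3326 ± 58.2. The interleukin-7 receptor IL7R of T cells fell from 2339.9 ± 299 to 963 ± 5.23 (log2 fold change -1.26, SE 0.25, adjusted p = 0.0177). 9 of 26 macrophage differentiation genes rose (16 adjusted over the list alone, median log2 0.60, camera adjusted p = 6.1e-15). 3 of 19 lysosome genes rose (13 adjusted over the list alone, median log2 0.42, camera adjusted p = 3.24e-12). 3 of 11 LXR target and cholesterol efflux genes rose (5 adjusted over the list alone, median log2 0.59, camera adjusted p = 7.87e-08), with NPC1 (0.80) and NR1H3 (1.06) among them. 4 of 16 T cell markers fell (8 adjusted over the list alone, median log2 -0.68, camera adjusted p = 4.18e-11, adjusted p = 0.0954 with an estimated correlation), from 72.8% to 40.6% of the PBMC signal at the median. limma called 162 of 9638 genes tested, 117 higher and 45 lower. Camera called 15 of 27 lists, 5 of them with an estimated correlation. APOC1 lost its call without CCL2 1 (1.13), MSR1 without Macrophages 6d 1 (1.05) or CCL2 1 (1.11), and GPNMB, IL7R, NPC1 and NR1H3 each without Macrophages 6d 1, CCL2 1 or CCL2 2. The count was 10 without Macrophages 6d 1, 1 without CCL2 1 and 17 without CCL2 2. It was 2 with the T cell covariate and 17 without the trend.

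CXCL1, a chemokine that arrests monocytes on the vessel wall, was tested in the same way. CYP27A1 rose from 224 ± 53.9 to 1051 ± 85.8 (log2 fold change 2.18, SE 0.28, adjusted p = 0.000344), the cathepsin CTSL from 1285 ± 154 to 3050.4 ± 139, GPNMB from 1693 ± 69.1 to 4014 ± 194 and NR1H3 from 418 ± 70.6 to 1235 ± 61.8. IL7R fell from 2339.9 ± 299 to 744 ± 81.1 (log2 fold change -1.63, SE 0.25, adjusted p = 0.00104), as did the NK and T cell lectin KLRB1 (from 637 ± 90.9 to 251 ± 46.7). 9 of 19 lysosome genes rose (18 adjusted over the list alone, median log2 0.56, camera adjusted p = 1.93e-18). 13 of 26 macrophage differentiation genes rose (18 adjusted over the list alone, median log2 0.75, camera adjusted p = 7.09e-18). 5 of 11 LXR target and cholesterol efflux genes rose (7 adjusted over the list alone, median log2 0.84, camera adjusted p = 7.14e-10), with NPC1 (1.06), NPC2 (0.69), APOC1 (1.14) and ABCG1 (1.09) among them. 6 of 16 T cell markers fell (11 adjusted over the list alone, median log2 -0.76, camera adjusted p = 8.75e-10, adjusted p = 0.114 with an estimated correlation), from 72.8% to 37.6% of the PBMC signal at the median. limma called 416 of 9638 genes tested, 291 higher and 125 lower. Camera called 13 of 27 lists, 7 of them with an estimated correlation. The count was 71 without Macrophages 6d 1, 145 without CXCL1 1 and 88 without CXCL1 2, 266 without the trend in the variance prior and 4 with the T cell marker level as a covariate. With a common median, 90.5% of the called genes were higher.

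Between the chemokines no single gene was called: limma called 0 of 9638 genes between CCL2 and CXCL1, with 809 at an unadjusted p under 0.05. 0 of 19 lysosome genes passed the test (2 lower adjusted over the list alone, 0 higher and 3 lower at an unadjusted p under 0.05 by limma, median log2 -0.17, camera adjusted p = 0.000387, adjusted p = 0.572 with an estimated correlation), the 1 list called by camera. Both comparisons share the 2 arrays of untreated macrophages: 99 genes rose with both, against 3.53 for independent calls, 26 fell with both, against 0.584, and 0 moved in opposite directions. The correlation of the log2 fold changes across genes, which are not independent replicates, was 0.635, against 0.50 in 100 simulated pairs of unchanged groups with shared controls. The covariance was 0.101, or 0.0585 above the simulated mean.

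**Figure D2:**
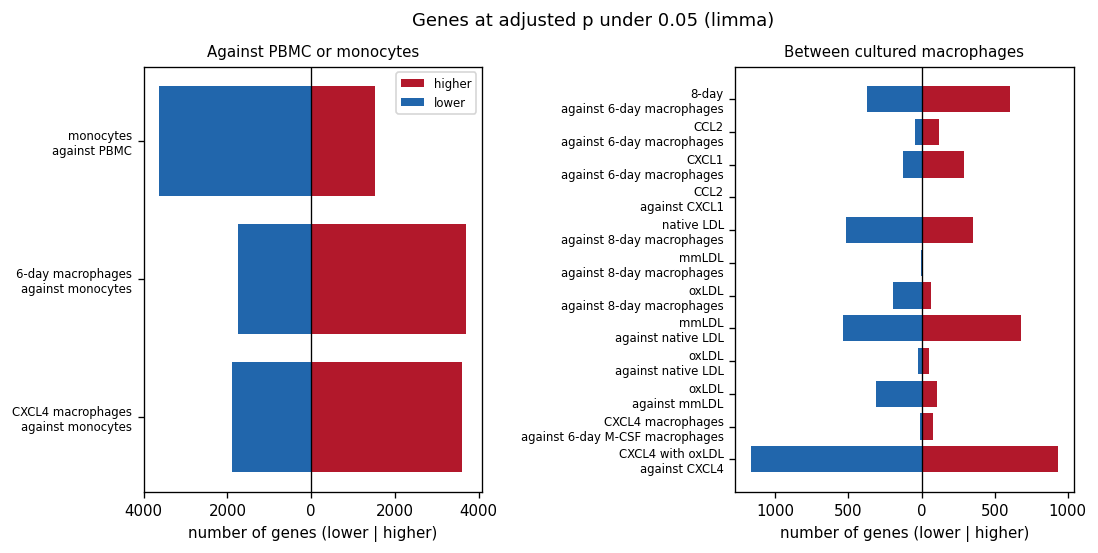
Number of genes called at an adjusted p under 0.05 (x axis, higher to the right in red and lower to the left in blue) for each comparison of a pair of groups (y axis). Comparisons against PBMC or monocytes are on the left and those between cultured macrophages on the right. Between cultures the counts ran from 0 (CCL2 against CXCL1) to 2104 (CXCL4 with oxLDL against CXCL4).

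Lipoprotein loading was compared with 8-day macrophages to see what foam cell formation changes. With native LDL, genes of cholesterol synthesis fell, such as the sterol-regulated gene INSIG1 (from 1439 ± 194 to 382 ± 34.8, log2 fold change -1.87, SE 0.16, adjusted p = 6.55e-07), MSMO1 (from 892 ± 236 to 238 ± 55.4) and the farnesyl diphosphate synthase FDPS (from 1186 ± 253 to 375 ± 137). The cholesterol exporter ABCG1 rose from 509.6 ± 204 to 1147 ± 25.4 (log2 fold change 1.21, SE 0.19, adjusted p = 0.000375), as did ABCA1 (from 551 ± 86.2 to 1109 ± 33.0) and PLIN2 (from 2772 ± 403 to 6272 ± 212). Stress genes rose too, including haem oxygenase HMOX1 (from 859 ± 413 to 4818 ± 157, log2 fold change 2.55, SE 0.30, adjusted p = 3.03e-05) and the glutathione synthesis gene GCLM (from 628 ± 168 to 1617 ± 4.10). Interferon-induced genes fell, such as MX1 (from 1285 ± 29.0 to 291 ± 114, log2 fold change -2.14, SE 0.17, adjusted p = 6.55e-07) and IFIT1 (from 233 ± 10.2 to 15.8 ± 3.04). CSF1R fell from 395 ± 100.2 to 133 ± 18.2 and the retinoic acid enzyme ALDH1A2 rose from 251 ± 3.68 to 1426 ± 212.

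10 of 18 cholesterol synthesis and uptake genes fell (12 adjusted over the list alone, median log2 -0.97, camera adjusted p = 3.96e-14). 1 of 20 interferon-stimulated genes rose and 14 fell (1 and 16 adjusted over the list alone, median log2 -0.86, camera adjusted p = 7.22e-16). 7 of 7 metallothioneins rose (same adjusted over the list alone, median log2 1.32, camera adjusted p = 3.01e-12). 6 of 14 oxidative stress response genes rose (11 adjusted over the list alone, median log2 0.59, camera adjusted p = 1.59e-07). 2 of 19 inflammatory cytokine and NF-kB target genes rose and 5 fell (2 and 7 adjusted over the list alone, median log2 -0.38, camera adjusted p = 0.00304, adjusted p = 0.086 with an estimated correlation): TNF (-1.81) and NFKBIA (-1.17) fell and CXCL8 (2.03) rose. 3 of 11 LXR target and cholesterol efflux genes rose and 1 fell (4 and 2 adjusted over the list alone, median log2 -0.08 and mean 0.09, tested upward, camera adjusted p = 0.323). 0 of 27 dendritic cell markers passed the test (0 adjusted over the list alone, 1 higher and 4 lower at an unadjusted p under 0.05 by limma, median log2 -0.11, camera adjusted p = 0.178), with CCL22 at 1629 ± 329 against 2355 ± 328 (adjusted p = 0.187). 1 of 12 MHC class II genes fell (same adjusted over the list alone, median log2 0.10 and mean -0.13, tested upward, camera adjusted p = 0.979). 2 of 15 ER stress and amino acid response genes rose (3 adjusted over the list alone, median log2 0.23, camera adjusted p = 0.0712). 7 of 11 NK cell markers fell (8 adjusted over the list alone, median log2 -0.83, camera adjusted p = 8.46e-09, adjusted p = 0.0778 with an estimated correlation). 5 of 16 T cell markers fell (6 adjusted over the list alone, median log2 -0.51, camera adjusted p = 2.06e-05, adjusted p = 0.265 with an estimated correlation), the T cell markers from 54.2% to 40.4% of the PBMC signal at the median, though LDL 2 (mean log2 9.05) lay between the control arrays. limma called 865 of 9638 genes tested, 349 higher and 516 lower. Camera called 12 of 27 lists, 4 of them with an estimated correlation. The count was 445 without Macrophages 8d 2 and 490 without LDL 2, 277 from the 4 arrays alone and 421 with the T cell marker level as a covariate. The higher share was 40.3%, and 23.7% with a common median.

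mmLDL left few calls. The fatty acid synthase FASN fell from 373 ± 21.3 to 154 ± 17.5 (log2 fold change -1.21, SE 0.20, adjusted p = 0.026), the nucleotide receptor P2RX7 from 756 ± 11.9 to 373 ± 3.89, the metallothionein MT1X from 3799 ± 34.6 to 2144 ± 25.1 and the chemokine CCL4 from 4618 ± 735 to 2468 ± 134. The granzyme GZMH rose from 725 ± 272 to 1819.7 ± 348 (log2 fold change 1.35, SE 0.25, adjusted p = 0.0379). 0 of 18 cholesterol synthesis and uptake genes passed the test (8 lower adjusted over the list alone, 0 higher and 10 lower at an unadjusted p under 0.05 by limma, median log2 -0.46, camera adjusted p = 1.5e-10). INSIG1 itself was 986 ± 143 against 1439 ± 194. 0 of 27 dendritic cell markers passed the test (1 lower adjusted over the list alone, 1 higher and 2 lower at an unadjusted p under 0.05 by limma, median log2 -0.09, camera adjusted p = 0.518), with CCL22 at 2286 ± 232 against 2355 ± 328 (adjusted p = 0.987). T cell markers stood at 43.0% of the PBMC signal at the median, and NK cell markers at 142%, against 54.2% and 110.5% in the controls. The mean T cell marker levels on the mmLDL arrays (9.12 and 9.36, log2) lay between those of the control arrays, and camera did not call the list (adjusted p = 0.442). limma called 7 of 9638 genes tested, 1 higher and 6 lower. Camera called 12 of 27 lists, 1 of them with an estimated correlation, and 793 genes had an unadjusted p under 0.05. The other genes called were the stress genes PMAIP1 (from 1001 ± 141 to 492 ± 8.84) and PPP1R15A (from 339 ± 58.7 to 168 ± 9.33). The count was 42 without Macrophages 8d 1, 0 without Macrophages 8d 2, 0 without mmLDL 1 and 0 without mmLDL 2, so that each call was lost without 3 of the arrays in turn, and 0 from the 4 arrays alone.

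With oxLDL, cholesterol synthesis genes fell too. INSIG1 went from 1439 ± 194 to 257 ± 56.4 (log2 fold change -2.43, SE 0.16, adjusted p = 1.84e-08), the last enzyme of the pathway DHCR7 from 379 ± 0.0707 to 61.1 ± 15.5 and MSMO1 from 892 ± 236 to 166 ± 7.78. Metallothioneins rose, MT1G going from 1484 ± 44.3 to 7152 ± 1981 (log2 fold change 2.23, SE 0.17, adjusted p = 1.16e-07) and MT1X from 3799 ± 34.6 to 11630.0 ± 2156. ABCG1 rose from 509.6 ± 204 to 1358 ± 22.4 (log2 fold change 1.45, SE 0.19, adjusted p = 0.000144) and ABCA1 from 551 ± 86.2 to 1243 ± 10.5. The fractalkine receptor CX3CR1 fell from 563 ± 41.6 to 236 ± 23.1 and CXCL10 from 891 ± 226 to 210.3 ± 151.

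11 of 18 cholesterol synthesis and uptake genes fell (14 adjusted over the list alone, median log2 -1.13, camera adjusted p = 4e-27). 7 of 7 metallothioneins rose (same adjusted over the list alone, median log2 2.08, camera adjusted p = 8.64e-28). 5 of 20 interferon-stimulated genes fell (9 adjusted over the list alone, median log2 -0.46, camera adjusted p = 1.03e-08). 10 of 16 proliferation genes fell (11 adjusted over the list alone, median log2 -0.86, camera adjusted p = 1.19e-16), including RRM2 (-1.56). 3 of 26 macrophage differentiation genes rose and 1 fell (4 and 1 adjusted over the list alone, median log2 0.27, camera adjusted p = 0.0054, adjusted p = 0.271 with an estimated correlation), a direction that turned with the T cell covariate (camera adjusted p = 0.708). 2 of 27 dendritic cell markers fell (5 adjusted over the list alone, median log2 -0.01, camera adjusted p = 0.315): the homing receptor CCR7 fell from 1204 ± 448 to 598 ± 42.0, a call lost without Macrophages 8d 2 (-0.56), oxLDL 1 (-0.88) or oxLDL 2 (-1.02). 1 of 12 MHC class II genes fell (same adjusted over the list alone, median log2 0.14 and mean -0.03, tested upward, camera adjusted p = 0.248). 6 of 11 NK cell markers fell (11 adjusted over the list alone, median log2 -0.95, camera adjusted p = 1.79e-13). 4 of 16 T cell markers fell (12 adjusted over the list alone, median log2 -0.75, camera adjusted p = 2.22e-09, adjusted p = 0.107 with an estimated correlation), the T cell markers from 54.2% to 31.6% of the PBMC signal at the median. limma called 264 of 9638 genes tested, 68 higher and 196 lower. Camera called 16 of 27 lists, 8 of them with an estimated correlation. The count was 424 without Macrophages 8d 1, 58 without Macrophages 8d 2 and 55 without oxLDL 2, 61 from the 4 arrays alone and 25 with the T cell marker level as a covariate. The labels of these arrays call the preparation minimally oxidized in 1 place, which leaves the degree of oxidation open.

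**Figure D3:**
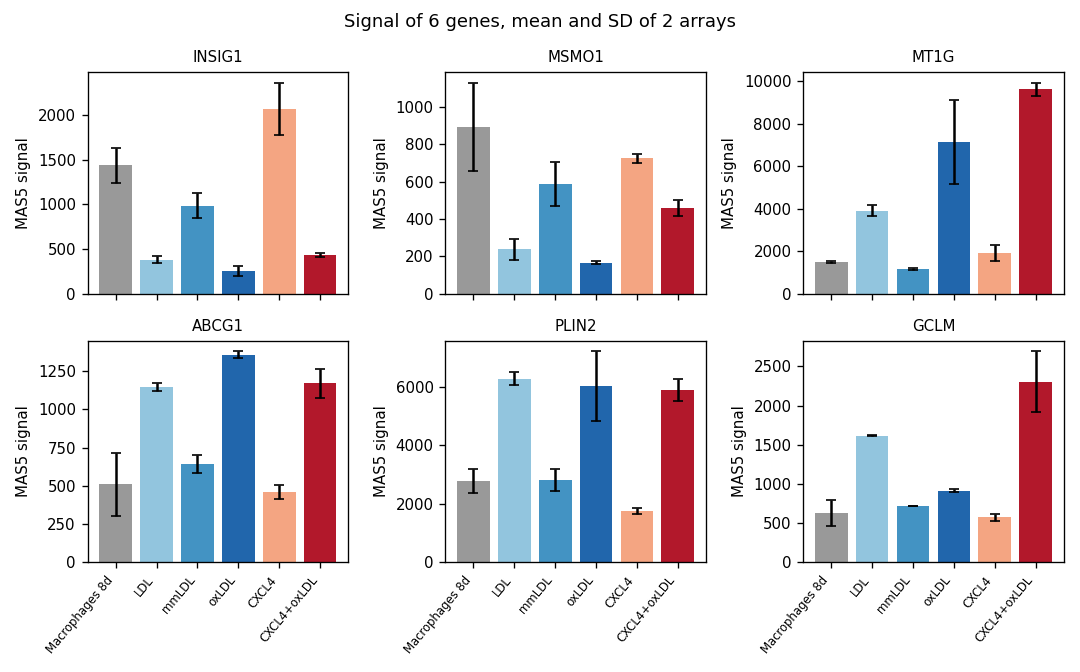
Signal (MAS5 intensity, y axis from 0) of INSIG1, MSMO1, MT1G, ABCG1, PLIN2 and GCLM in 8-day macrophages, with native LDL, mmLDL or oxLDL, and with CXCL4 without and with oxLDL (x axis), bars giving the mean and error bars the SD of 2 arrays. INSIG1 was 1439 ± 194 in 8-day macrophages, 382 ± 34.8 with native LDL and 257 ± 56.4 with oxLDL.

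Between preparations, mmLDL and native LDL differed most. With mmLDL, S100A8 was higher (from 526 ± 419 to 2901 ± 208, log2 fold change 2.69, SE 0.47, adjusted p = 0.000899), as were CCL2 (from 185 ± 185 to 1500.0 ± 482), the RNA sensor TLR8 (from 6.60 ± 5.09 to 183 ± 2.76) and IFIT1 (from 15.8 ± 3.04 to 233 ± 26.4), each given from native LDL to mmLDL. CXCL8 was lower (from 4409 ± 229 to 696 ± 190.1, log2 fold change -2.66, SE 0.28, adjusted p = 8.2e-06), as were HMOX1 (from 4818 ± 157 to 1243 ± 132), the stress cytokine GDF15 (from 1211 ± 175 to 229 ± 0.849) and PLIN2 (from 6272 ± 212 to 2812 ± 374). INSIG1 was higher (from 382 ± 34.8 to 986 ± 143), and CSF1R was higher (from 133 ± 18.2 to 527 ± 86.1). 7 of 7 metallothioneins fell (same adjusted over the list alone, median log2 -1.73, camera adjusted p = 1.1e-13). 12 of 20 interferon-stimulated genes rose and 1 fell (16 and 2 adjusted over the list alone, median log2 0.85, camera adjusted p = 5.35e-12). 6 of 18 cholesterol synthesis and uptake genes rose (same adjusted over the list alone, median log2 0.35, camera adjusted p = 8.49e-05). 7 of 14 oxidative stress response genes fell (10 adjusted over the list alone, median log2 -0.60, camera adjusted p = 8.11e-07). 15 of 16 proliferation genes rose (same adjusted over the list alone, median log2 1.03, camera adjusted p = 1.18e-15), including TOP2A (1.63) and CCNA2 (1.41). 2 of 27 dendritic cell markers rose (same adjusted over the list alone, median log2 0.01, camera adjusted p = 0.64), the lectin CD209 (DC-SIGN) being higher (from 291 ± 43.8 to 572 ± 78.1) but losing its call without LDL 2 (0.80), mmLDL 1 (1.08) or mmLDL 2 (0.81). 7 of 11 NK cell markers rose (9 adjusted over the list alone, median log2 1.02, camera adjusted p = 5.09e-10, adjusted p = 0.0517 with an estimated correlation). 3 of 16 T cell markers rose (6 adjusted over the list alone, median log2 0.49, camera adjusted p = 0.000862, adjusted p = 0.471 with an estimated correlation), at 40.4% of the PBMC signal with native LDL and 43.0% with mmLDL. limma called 1220 of 9638 genes tested, 684 higher and 536 lower. Camera called 11 of 27 lists, 5 of them with an estimated correlation. The count was 636 without LDL 2, 500 without mmLDL 1 and 505 without mmLDL 2. The higher share was 56.1%, and 79.1% with a common median.

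oxLDL and native LDL differed in fewer genes. MX1 was higher with oxLDL (from 291 ± 114 to 658 ± 19.7, log2 fold change 1.19, SE 0.17, adjusted p = 0.00128), as were TLR8 (from 6.60 ± 5.09 to 97.0 ± 49.1) and IFIT1 (from 15.8 ± 3.04 to 211 ± 11.1). ALDH1A2 was lower (from 1426 ± 212 to 463 ± 108, log2 fold change -1.61, SE 0.20, adjusted p = 0.000446), each given from native LDL to oxLDL. The antiviral gene RSAD2 went the other way from MX1 (from 1834 ± 227 to 652 ± 32.9) and lost its call without oxLDL 1 (-1.42). 5 of 20 interferon-stimulated genes rose and 1 fell (8 and 1 adjusted over the list alone, median log2 0.55, camera adjusted p = 2.06e-10). 2 of 7 metallothioneins rose (6 adjusted over the list alone, median log2 0.62, camera adjusted p = 1.21e-08). 0 of 27 dendritic cell markers passed the test (0 adjusted over the list alone, 1 higher and 1 lower at an unadjusted p under 0.05 by limma, median log2 0.10, camera adjusted p = 0.594), with CCL22 at 1484 ± 751 against 1629 ± 329 (adjusted p = 0.765). T cell markers stood at 31.6% of the PBMC signal at the median with oxLDL and 40.4% with native LDL. limma called 74 of 9638 genes tested, 53 higher and 21 lower. Camera called 9 of 27 lists, 3 of them with an estimated correlation. The count was 146 without LDL 1, 8 without LDL 2 and 11 without oxLDL 1, 2 from the 4 arrays alone and 20 without the trend in the variance prior. The higher share was 71.6%, and 92.8% with a common median.

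oxLDL against mmLDL gave a metallothionein difference, MT1X going from 2144 ± 25.1 to 11630.0 ± 2156 (log2 fold change 2.42, SE 0.14, adjusted p = 3.76e-09) and MT1G from 1168 ± 59.8 to 7152 ± 1981 from mmLDL to oxLDL. INSIG1 was lower (from 986 ± 143 to 257 ± 56.4, log2 fold change -1.89, SE 0.16, adjusted p = 4.02e-07), as was MSMO1 (from 586 ± 118 to 166 ± 7.78), and PLIN2 was higher (from 2812 ± 374 to 6015 ± 1184). The NK cell markers GZMA (from 2101 ± 35.4 to 444 ± 76.5) and NKG7 (from 2124 ± 153 to 807 ± 22.1) were lower. 7 of 7 metallothioneins rose (same adjusted over the list alone, median log2 2.42, camera adjusted p = 8.91e-29). 8 of 18 cholesterol synthesis and uptake genes fell (9 adjusted over the list alone, median log2 -0.44, camera adjusted p = 2.91e-12). 14 of 16 proliferation genes fell (15 adjusted over the list alone, median log2 -1.39, camera adjusted p = 1.35e-28). 1 of 27 dendritic cell markers rose and 1 fell (same adjusted over the list alone, median log2 -0.02 and mean 0.01, tested downward, camera adjusted p = 0.724): LAMP3 (0.78) rose and CD200 (-0.94) fell, the calls lost without mmLDL 1 (0.86), mmLDL 2 (0.70) or oxLDL 2 (0.69) and without mmLDL 1 (-1.01), mmLDL 2 (-0.86) or oxLDL 2 (-0.78), respectively. 9 of 11 NK cell markers fell (10 adjusted over the list alone, median log2 -1.13, camera adjusted p = 3.2e-15). 3 of 16 T cell markers fell (11 adjusted over the list alone, median log2 -0.67, camera adjusted p = 8.31e-07, adjusted p = 0.187 with an estimated correlation), at 43.0% of the PBMC signal with mmLDL and 31.6% with oxLDL. limma called 415 of 9638 genes tested, 104 higher and 311 lower. Camera called 11 of 27 lists, 8 of them with an estimated correlation. The count was 148 without mmLDL 1, 144 without mmLDL 2 and 142 without oxLDL 2, and 165 with the T cell marker level as a covariate.

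The 3 lipoprotein effects share the 2 arrays of 8-day macrophages. Native LDL and oxLDL moved genes together: 56 rose with both, against 2.46 for independent calls, 127 fell with both, against 10.5, and 0 moved in opposite directions. Their log2 fold changes correlated at 0.647 across genes, against 0.50 in 100 simulated pairs of unchanged groups with the same controls, and the covariance exceeded the simulated mean by 0.0899. Native LDL and mmLDL correlated at 0.222, below the simulated 0.501, with 3 genes falling with both and 3 moving in opposite directions, and the covariance lay at -0.00564 from the simulated mean. mmLDL and oxLDL correlated at 0.349, where unchanged groups again gave 0.501, with 3 genes falling with both and 2 moving in opposite directions. Their covariance lay 0.00311 above the simulated mean (SD over simulations 0.00137). These are 3 correlations across genes, which are not independent replicates.

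Culture with CXCL4, a platelet chemokine given in place of M-CSF, was compared with isolated monocytes. Here too lymphocyte transcripts differed, so a change of cell mix is not separated. CD14 fell from 9838 ± 1101 to 78.3 ± 14.4 (log2 fold change -6.75, SE 0.29, adjusted p = 3.19e-13), the chemokine CXCL2 from 8816 ± 617 to 20.3 ± 4.10 and PTGS2 from 6796 ± 406 to 21.6 ± 11.0. APOC1 rose from 22.9 ± 4.81 to 2409.9 ± 359 (log2 fold change 6.05, SE 0.15, adjusted p = 4.03e-16), MRC1 from 51.7 ± 4.38 to 2763 ± 368 and NR1H3 from 48.4 ± 18.3 to 862 ± 249. The dendritic cell chemokine CCL22 rose from 213 ± 12.3 to 4874 ± 285 and the lysosomal protein LAMP3 from 106 ± 3.96 to 579 ± 55.7. 1 of 19 inflammatory cytokine and NF-kB target genes rose and 18 fell (same adjusted over the list alone, median log2 -2.79, camera adjusted p = 3.88e-13). 1 of 14 monocyte markers rose and 10 fell (same adjusted over the list alone, median log2 -3.19, camera adjusted p = 2.4e-07). 16 of 16 proliferation genes rose (same adjusted over the list alone, median log2 3.41, camera adjusted p = 1.82e-10). 16 of 26 macrophage differentiation genes rose and 9 fell (same adjusted over the list alone, median log2 1.26, camera adjusted p = 0.133). 15 of 27 dendritic cell markers rose and 5 fell (same adjusted over the list alone, median log2 0.89, camera adjusted p = 0.272). 16 of 16 T cell markers rose (same adjusted over the list alone, median log2 2.35, camera adjusted p = 2.18e-06, adjusted p = 0.181 with an estimated correlation), from 6.99% to 39.6% of the PBMC signal at the median. limma called 5510 of 9638 genes tested, 3607 higher and 1903 lower. Camera called 17 of 27 lists, 8 of them with an estimated correlation. The median log2 fold change of all genes was 0.18 under the deposited scaling, 0.06 after quantile normalization and 0.08 with a common median.

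Set against M-CSF macrophages of the same age, CXCL4 macrophages had more ABCG1 (from 156 ± 2.26 to 458 ± 47.0, log2 fold change 1.47, SE 0.19, adjusted p = 0.00153), more of the prostaglandin synthase PTGDS (from 272 ± 41.3 to 821 ± 55.8), more APOC1 (from 1296 ± 80.4 to 2409.9 ± 359) and more RSAD2 (from 923 ± 342 to 2117 ± 60.1), each given from M-CSF to CXCL4. 4 of 11 LXR target and cholesterol efflux genes rose (10 adjusted over the list alone, median log2 0.88, camera adjusted p = 1.34e-14). 3 of 20 interferon-stimulated genes rose (6 adjusted over the list alone, median log2 0.47, camera adjusted p = 1.45e-09). 0 of 27 dendritic cell markers passed the test (0 adjusted over the list alone, 4 higher and 0 lower at an unadjusted p under 0.05 by limma, median log2 0.21, camera adjusted p = 0.0282, adjusted p = 0.253 with an estimated correlation). 1 of 16 T cell markers fell (10 adjusted over the list alone, median log2 -0.60, camera adjusted p = 7.31e-11, adjusted p = 0.13 with an estimated correlation), at 72.8% of the PBMC signal with M-CSF and 39.6% with CXCL4. limma called 88 of 9638 genes tested, 76 higher and 12 lower. Camera called 12 of 27 lists, 3 of them with an estimated correlation. ABCG1 and PTGDS lost their calls without CXCL4 2, and APOC1 and RSAD2 also without Macrophages 6d 1. The count was 6 without Macrophages 6d 1 and 0 without CXCL4 2. It was 0 with the T cell covariate, against 1171 at an unadjusted p under 0.05 without it, and 30 without the trend. 6-day controls that stand apart stay open.

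The effect of oxLDL after CXCL4 was read from CXCL4 with oxLDL against CXCL4 alone. Lipid storage genes rose, with the nuclear receptor PPARG going from 132 ± 8.77 to 629 ± 35.5 (log2 fold change 2.14, SE 0.19, adjusted p = 2.38e-07) and PLIN2 from 1750.0 ± 94.8 to 5887 ± 376. Stress genes rose, including GCLM (from 572 ± 47.6 to 2303 ± 389, log2 fold change 1.98, SE 0.16, adjusted p = 8.69e-08), HMOX1 (from 1021 ± 26.9 to 6028 ± 807) and MT1G (from 1921 ± 387 to 9620.1 ± 299.8). INSIG1 fell from 2069.5 ± 293 to 433 ± 19.4 (log2 fold change -2.22, SE 0.16, adjusted p = 3.56e-08) and the squalene epoxidase SQLE from 1426 ± 329 to 362 ± 111. CXCL10 fell from 1649 ± 212 to 174 ± 49.6 (log2 fold change -3.17, SE 0.32, adjusted p = 8.99e-07), CCL1 from 1494 ± 291 to 55.0 ± 64.8 and MS4A1 from 1546 ± 87.7 to 155 ± 11.0.

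7 of 7 metallothioneins rose (same adjusted over the list alone, median log2 1.95, camera adjusted p = 9.82e-12). 10 of 14 oxidative stress response genes rose (same adjusted over the list alone, median log2 0.91, camera adjusted p = 4.67e-08). 6 of 15 PPAR target and lipid storage genes rose and 1 fell (7 and 1 adjusted over the list alone, median log2 0.43, camera adjusted p = 0.000121). 11 of 18 cholesterol synthesis and uptake genes fell (13 adjusted over the list alone, median log2 -0.71, camera adjusted p = 1.71e-08). 15 of 19 lysosome genes rose (18 adjusted over the list alone, median log2 0.64, camera adjusted p = 7.27e-10). 13 of 16 proliferation genes fell (15 adjusted over the list alone, median log2 -1.38, camera adjusted p = 2.52e-15). 4 of 11 scavenger receptors rose (same adjusted over the list alone, median log2 0.76, camera adjusted p = 0.00162, adjusted p = 0.0762 with an estimated correlation), including CD36 (1.27) and MSR1 (1.09). 3 of 27 dendritic cell markers rose and 8 fell (3 and 9 adjusted over the list alone, median log2 -0.33, camera adjusted p = 0.0101, adjusted p = 0.125 with an estimated correlation): ITGAX rose from 411 ± 0.0707 to 1501 ± 385, and CCR7 fell from 1637 ± 203 to 444 ± 45.0, the actin bundler FSCN1 from 406 ± 31.5 to 103 ± 23.2 and CD200 from 165 ± 0.778 to 45.4 ± 5.59. 2 of 12 MHC class II genes rose and 1 fell (3 and 1 adjusted over the list alone, median log2 0.30, camera adjusted p = 0.223). 10 of 11 NK cell markers fell (11 adjusted over the list alone, median log2 -1.56, camera adjusted p = 2.92e-12). 7 of 10 B cell markers fell (1 and 7 adjusted over the list alone, median log2 -1.74, camera adjusted p = 1.19e-06). 1 of 16 T cell markers rose and 12 fell (1 and 14 adjusted over the list alone, median log2 -1.39, camera adjusted p = 4.94e-10, adjusted p = 0.0762 with an estimated correlation), the T cell markers from 39.6% to 18.5% of the PBMC signal at the median. limma called 2104 of 9638 genes tested, 935 higher and 1169 lower. Camera called 14 of 27 lists, 10 of them with an estimated correlation. The count was 1158 without CXCL4 1 and 1243 without CXCL4+oxLDL 2, and 156 with the T cell marker level as a covariate. Here too culture time and oxLDL are not separated.

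The difference between the oxLDL effect after CXCL4 and that after M-CSF was tested. Its controls differed in age (6 days for CXCL4, 8 for M-CSF), and the total time with oxLDL is not given, so culture time is not separated. The B cell marker MS4A1 fell with oxLDL after CXCL4, from 1546 ± 87.7 to 155 ± 11.0, and was 510.3 ± 75.9 without and 342 ± 41.6 with oxLDL after M-CSF (log2 difference -2.65, SE 0.32, adjusted p = 3e-04). The stress protein NUPR1 rose after CXCL4, from 103 ± 28.4 to 849 ± 27.6, and was 742 ± 76.4 and 1064 ± 288 after M-CSF (log2 difference 2.41, SE 0.32, adjusted p = 0.00117), but with 6-day M-CSF macrophages as the control the difference was -0.34. MSMO1 was 724 ± 25.9 and 459 ± 43.6 after CXCL4 and fell from 892 ± 236 to 166 ± 7.78 after M-CSF (log2 difference 1.67, SE 0.27, adjusted p = 0.00775). GCLM rose from 572 ± 47.6 to 2303 ± 389 after CXCL4 and was 628 ± 168 and 912 ± 18.9 after M-CSF (log2 difference 1.42, SE 0.22, adjusted p = 0.00478), a call lost without CXCL4+oxLDL 2.

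0 of 19 lysosome genes passed the test (4 higher adjusted over the list alone, 8 higher and 0 lower at an unadjusted p under 0.05 by limma, median log2 difference 0.48, camera adjusted p = 9.79e-09). 3 of 10 B cell markers had a lower effect (7 adjusted over the list alone, median log2 difference -1.21, camera adjusted p = 6.65e-08). 0 of 26 macrophage differentiation genes passed the test (6 higher adjusted over the list alone, 9 higher and 0 lower at an unadjusted p under 0.05 by limma, median log2 difference 0.47, camera adjusted p = 3.19e-05, adjusted p = 0.155 with an estimated correlation). 0 of 27 dendritic cell markers passed the test (0 adjusted over the list alone, 1 higher and 6 lower at an unadjusted p under 0.05 by limma, median log2 difference -0.40, camera adjusted p = 0.01, adjusted p = 0.155 with an estimated correlation). limma called 31 of 9638 genes, 9 with a higher and 22 with a lower effect after CXCL4, the T cell markers being lowest among the cultures with CXCL4 and oxLDL (18.5% of the PBMC signal at the median). The count was 14 without oxLDL 1, 55 without oxLDL 2, 16 without CXCL4 1, 53 without CXCL4+oxLDL 1 and 9 without CXCL4+oxLDL 2, and 11 from the 8 arrays of these groups alone. With 6-day M-CSF macrophages as the control it was 35, and 4 genes were called the same way with both controls, among them MS4A1 (-1.46), MSMO1 (1.47) and GCLM (1.34). Of the 31, 26 kept their direction, and of the 10 lists called 2 stayed called in the same direction. Among the 10 lists, the medians turned to -0.36 (camera adjusted p = 5.52e-08) for lysosome and -0.59 (camera adjusted p = 2.31e-12) for macrophage differentiation. They were -0.35 (camera adjusted p = 0.0545) for B cell and -0.30 (camera adjusted p = 0.0545) for dendritic cell markers.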

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

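The tests below, other than those of the difference of effects with the 8-day control and of chance values of the shared control arrays, were chosen only after the results were seen. The change from CXCL4 to CXCL4 with oxLDL differed from that from 8-day M-CSF macrophages to oxLDL, by limma's test of the difference, in 31 of 9638 genes. The CXCL4 control was of 6 days, so culture time is not separated. Lower after CXCL4 were CCL1 (-3.26), IGLV1-44 (-2.95), MS4A1 (-2.65), MEF2C (-2.63), JCHAIN (-2.53) and RGS16 (-2.35) as log2 differences, among them genes of B and plasma cells, and higher were NUPR1 (2.41), MSMO1 (1.67), CLIP2 (1.58), DTX4 (1.49), GCLM (1.42) and PLPP3 (1.31). IGLV1-44 and JCHAIN lay below background with CXCL4 and oxLDL, as did CCL1 on 1 of the arrays, so that their differences depend on the offset. By list, the median log2 difference was 0.47 (camera adjusted p = 3.19e-05, adjusted p = 0.155 with an estimated correlation) for macrophage differentiation, -0.40 (camera adjusted p = 0.01, adjusted p = 0.155 with an estimated correlation) for dendritic cell markers, 0.20 (camera adjusted p = 0.0116, adjusted p = 0.107 with an estimated correlation) for cholesterol synthesis and uptake, and 0.59 (camera adjusted p = 0.0263, adjusted p = 0.255 with an estimated correlation) for scavenger receptors. It was 0.27 (camera adjusted p = 0.000635, adjusted p = 0.155 with an estimated correlation) for oxidative stress response, 0.48 (camera adjusted p = 9.79e-09) for lysosome and -0.63 (camera adjusted p = 5.68e-08, adjusted p = 0.107 with an estimated correlation) for proliferation genes. For lymphocyte markers it was -0.65 (camera adjusted p = 2.83e-05, adjusted p = 0.281 with an estimated correlation) for T cells, -1.21 (camera adjusted p = 6.65e-08) for B cells and -0.57 (camera adjusted p = 7.07e-06, adjusted p = 0.155 with an estimated correlation) for NK cells. With 6-day M-CSF macrophages as the control, 35 genes were called, 4 of them also among the 31 in the same direction, while 26 of the 31 kept their direction; NUPR1, DTX4 and PLPP3 turned to -0.34, -0.35 and -0.81. Of the 10 lists, 2 stayed called in the same direction, at medians of 0.25 (camera adjusted p = 0.0307, adjusted p = 0.0967 with an estimated correlation) for cholesterol synthesis and uptake and -0.45 (camera adjusted p = 5.96e-05, adjusted p = 0.178 with an estimated correlation) for NK cells. The others went to -0.59 (camera adjusted p = 2.31e-12) for macrophage differentiation, -0.36 (camera adjusted p = 5.52e-08) for lysosome, -0.33 (camera adjusted p = 0.0581) for scavenger receptors, -0.30 (camera adjusted p = 0.0545) for dendritic cell markers, -0.35 (camera adjusted p = 0.0545) for B cells, 0.03 (camera adjusted p = 0.65) for T cells, 0.00 (camera adjusted p = 0.836) for oxidative stress response and 0.00 (camera adjusted p = 0.674) for proliferation.

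T cell transcripts were high in 6-day macrophages, at a median of 72.8% of the PBMC signal, against 6.99% in the monocyte arrays, whose cells had been purified by negative selection and checked for CD14. The highest platelet marker reached 24.6% and the median one 2.11%, which argues against PBMC mixed in at harvest, as that would bring platelet transcripts in the share of the T cell ones; platelets lost during culture are not covered. Lymphocytes among the cultured cells stay open. All 16 T cell markers rose from monocytes, CD3D from 159 ± 22.1 to 3733 ± 123, which goes with them. The range, 32.9% to 374% of PBMC signal, cannot decide, as marker ratios may shift in culture. The labels name no T cell group, so no biological explanation was tested, and whether the monocyte arrays and the cultures came from the same isolation stays open.

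125 genes were called the same way with CCL2 and CXCL1, of 162 and 416 called. Chance values of the shared control arrays are argued against by the correlation across genes of 0.266 and 0.321 when each chemokine is set against its own control array. 6-day controls that stand apart as a group stay open: of 142 shared genes chosen against Macrophages 6d 1, 95.8% also moved that way with CXCL4 set against Macrophages 6d 2, where the directions of all genes give 47.3%, but the other assignment left 7 genes, too few to decide. Fewer T cells with the chemokines cannot be told apart from an effect of the chemokines: under the covariate the median size of the shared genes kept 64.0% of its value with CXCL1 and 66.1% with CCL2, going from 1.03 (SE 0.19) to 0.66 (SE 0.26) and from 0.90 (SE 0.19) to 0.59 (SE 0.24), so that calls ended through a smaller size and a larger SE. A shared response to the chemokines stays open, as untested.

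Native LDL stood apart from mmLDL more than from oxLDL, which is not the order of oxidation. 1 array alone is argued against, since at least 484 of the 1220 genes called stayed called in the same direction without any 1 of the 4 arrays. Fewer T cells as the whole cause stay open: the covariate's slope rests only on differences within pairs of arrays. Under it the median size of the 1220 kept 96.1%, from 0.87 (SE 0.20) to 0.83 (SE 0.22), and 781 stayed called. NK cell markers (70.6% of PBMC with native LDL, 142% with mmLDL) and proliferation are not covered. An exchange of the native LDL and mmLDL labels stays open: the 74 genes called between oxLDL and native LDL and the 415 between oxLDL and mmLDL are the pattern itself and give it no support. Samples were analysed as labelled, and native LDL oxidized in culture or other differences of preparation stay open, as untested.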

How the results depend on the processing

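The fits without the PBMC arrays, with the T cell covariate and with a 6-day M-CSF control were chosen after the data were seen. First run on every comparison, the covariate reversed many results against monocytes or PBMC, where the marker level follows the groups. After its values were seen, it was kept only between cultures and left out for the T cell list itself. Its counts still hold the T cell markers, so part of a drop can be built in. Of 957 called pairs of a named gene and a comparison, 613 kept their call in every setting fixed beforehand in which they were tested. Calls were lost for 28 pairs with quantile normalization, 79 with a common median, 59 without an offset, 10 with the larger offset, 72 without the low filter, 148 without the trend, 163 with the compared arrays alone, 18 with the replicate block, and in 890 of 3892 fits that left out 1 array. The covariate ended 344 of 617. Without the PBMC arrays 7 of 845 were lost, and no count of genes moved past 1.5 times its value. With the 6-day control, 10 of 16 calls in the difference of effects were lost and 3 kept. The labels do not say that the replicate numbers pair arrays. Over 55 pairs of groups the correlation of the replicate differences ran from -0.242 to 0.196 (median 0.00343), above 0.1 in 5 and above 0 for every pair among 8-day macrophages and the lipoprotein groups, and the replicate block moved no count of genes past 1.5 times. Where an array is left out, the lone array of its group is assumed to vary like the other groups. Signal near background limits what the arrays show: with no low filter or a filter at the 60th percentile the number of genes tested changes.

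Counts of genes that moved past 1.5 times were as follows, and the cause was not tested unless stated. With the probe sets tested one by one, which are more numerous than the genes, the counts were 8503 for monocytes against PBMC, 8872 for 6-day macrophages against monocytes, 8988 for CXCL4 against monocytes, 3309 for CXCL4 with oxLDL against CXCL4 and 58 for the difference of effects. With a 2-fold minimum, which can only remove calls, they were 2967 for monocytes against PBMC, 3541 for 6-day macrophages against monocytes, 330 for 8-day against 6-day macrophages, 57 for CCL2, 144 for CXCL1, 340 for native LDL, 2 for mmLDL, 112 for oxLDL, 444 for mmLDL against native LDL, 38 for oxLDL against native LDL, 200 for oxLDL against mmLDL, 3494 for CXCL4 against monocytes, 29 for CXCL4 against M-CSF and 813 for CXCL4 with oxLDL against CXCL4. With the compared arrays alone, and so with fewer arrays for the spread, they were 542 for 8-day against 6-day macrophages, 2 for CCL2 against CXCL1, 277 for native LDL, 0 for mmLDL, 61 for oxLDL, 2 for oxLDL against native LDL and 11 for the difference of effects. A common median gave 72 for CCL2, 2 for mmLDL and 170 for oxLDL. No low filter gave 107 for CCL2, 1 for CCL2 against CXCL1 and 2 for mmLDL. Without the trend they were 17 for CCL2, 266 for CXCL1, 2 for mmLDL, 163 for oxLDL, 20 for oxLDL against native LDL and 30 for CXCL4 against M-CSF. The difference of effects gave 61 genes with the larger offset and 48 with the filter at the 60th percentile. With the T cell marker level as a covariate the counts were 368 for 8-day against 6-day macrophages, 2 for CCL2, 4 for CXCL1, 421 for native LDL, 25 for oxLDL, 165 for oxLDL against mmLDL, 0 for CXCL4 against M-CSF and 156 for CXCL4 with oxLDL against CXCL4.

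Leaving out 1 array at a time gave 4422 to 4602 for monocytes against PBMC, 4769 to 4859 for 6-day macrophages against monocytes, 405 to 874 for 8-day against 6-day macrophages, 1 to 181 for CCL2, 71 to 308 for CXCL1, 0 to 1 for CCL2 against CXCL1, 445 to 714 for native LDL, 0 to 42 for mmLDL, 55 to 424 for oxLDL, 500 to 877 for mmLDL against native LDL, 8 to 146 for oxLDL against native LDL, 142 to 348 for oxLDL against mmLDL, 4644 to 5125 for CXCL4 against monocytes, 0 to 115 for CXCL4 against M-CSF, 1158 to 1787 for CXCL4 with oxLDL against CXCL4 and 9 to 55 for the difference of effects. Counts of lists called ranged over 9 to 15 for 8-day against 6-day macrophages, 0 to 5 for CCL2 against CXCL1, 7 to 12 for mmLDL against native LDL and 7 to 10 for CXCL4 against M-CSF.

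With an estimated correlation camera called 4 for monocytes against PBMC, 8 for 6-day macrophages against monocytes, 9 for 8-day against 6-day macrophages, 5 for CCL2, 7 for CXCL1, 0 for CCL2 against CXCL1, 4 for native LDL, 1 for mmLDL, 8 for oxLDL, 5 for mmLDL against native LDL, 3 for oxLDL against native LDL, 8 for CXCL4 against monocytes, 3 for CXCL4 against M-CSF and 2 for the difference of effects, out of 27 lists. fry called 0 for CCL2 against CXCL1, 3 for mmLDL, 4 for oxLDL against native LDL, 26 for CXCL4 against monocytes, 6 for CXCL4 against M-CSF and 6 for the difference of effects. With the covariate camera called 2 for CCL2, 4 for CXCL1, 9 for oxLDL, 7 for mmLDL against native LDL, 7 for CXCL4 against M-CSF, 9 for CXCL4 with oxLDL against CXCL4 and 5 for the difference of effects. Correlations between effects moved to 0.241 (quantile normalization) and 0.187 (larger offset) for native LDL and mmLDL, to 0.684 (larger offset) for native LDL and oxLDL, to 0.307 (larger offset) for mmLDL and oxLDL, and to 0.664 and 0.695 for CCL2 and CXCL1. The replicate block cannot change them in a balanced design. Reversed were MT1G in monocytes against PBMC with a common median (log2 fold change 0.45), HK2 (-0.29) and SPARC (-0.47) in CXCL4 with oxLDL against CXCL4 with the covariate, and the macrophage differentiation list with oxLDL with the covariate (adjusted p = 0.708). In the difference of effects the 6-day control, which is 2 days younger, reversed NUPR1 (-0.34), DTX4 (-0.35), PLPP3 (-0.81) and APOC1 (-1.69), and the lists for macrophage differentiation (adjusted p = 2.31e-12), scavenger receptors (0.0581), lysosome (5.52e-08) and proliferation (0.674). With a common median the 7 calls for mmLDL became 2, 0 of them higher. The median log2 fold change of all genes moved from 0.03 to -0.14 for CCL2 against CXCL1 and from -0.05 to 0.11 for oxLDL against native LDL.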

Other observations

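Receptors of the ligands given to the cells moved differently from monocytes to macrophages. CXCR2, a receptor for CXCL1, was 83.6 ± 14.8 in monocytes and below background in 6-day macrophages. CCR2, the receptor for CCL2, was 131 ± 16.6 in monocytes and 118 ± 10.1 in 6-day macrophages (adjusted p = 0.618). CXCR3, a receptor that binds CXCL4, rose between the same groups from 93.3 ± 37.4 to 273 ± 24.1 (log2 fold change 1.47, SE 0.27, adjusted p = 0.000111), alongside the T cell markers, which also carry it, and fell with oxLDL after CXCL4 from 230.2 ± 24.4 to 58.4 ± 13.9.

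Receptors for modified lipoproteins differed among themselves. The fatty acid and oxLDL receptor CD36 fell from monocytes to 6-day macrophages from 177 ± 14.1 to 85.8 ± 3.96 (log2 fold change -0.94, SE 0.21, adjusted p = 0.000738), and rose from there to 8 days from 85.8 ± 3.96 to 201 ± 43.6. The class A receptor MSR1 rose in both steps, from 48.6 ± 2.19 to 160.4 ± 37.1 and from 160.4 ± 37.1 to 436 ± 69.2, and with oxLDL after CXCL4 from 256 ± 31.3 to 558 ± 26.5.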
